A study of Mus musculus with 10 samples.

How the data were processed

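RNA was sequenced from pancreatic islets of 10 male C57BL/6J mice, a common inbred laboratory strain. Per the labels, the mice were 8 to 10 weeks old, were fed a western diet or standard chow for 4 weeks, and their islets were isolated and processed at once. Each diet has 5 libraries, with 1 library per mouse. The labels place all 5 chow mice in cage 3, 4 western diet mice in cage 4 and 1 western diet mouse in cage 2, so no cage held both diets.

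The authors deposited 1 table of 27665 genes. Its read counts per gene are whole numbers and not normalized, per the file headers and the values. STAR 2.5, HTSeq 2, DESeq2 and the mouse builds mm10 and GRCm38 are named in the submitters' processing notes, with no order of steps. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols, and the strand setting of the counting is not given in the sources used here. Reads from a gene and from an overlapping or antisense gene can therefore not be told apart. The same deposited table holds the authors' own comparison as log2 fold changes of western diet over chow. It also holds the authors' p-values, unadjusted and adjusted, for that comparison. In 88 genes the deposited unadjusted p-value is empty and the adjusted one is set to 1. A further 20 columns of normalized values and FPKM per sample were not used here.

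Gene names and coordinates are those of the deposited table. Of its gene identifiers, 27653 were also in GENCODE M21, an annotation of GRCm38, and 26881 of these had the same chromosome, start and end. That annotation was used to find genes that lie in an intron of another gene or within 5 kb downstream of it.

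The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15104, and libraries were scaled with TMM factors. A quasi-likelihood model with robust moderation compared the diets with no covariate. The p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are western diet over chow, and their standard errors (SE) are the size of the log2 fold change divided by the root of the F statistic. CPM are counts scaled to library size with the TMM factors, as edgeR computes them. Total counts were 1.65e+07 to 2.39e+07 per library. The spread given with each value is that between mice and includes counting error, except for bootstrap SE, which are over genes.

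Gene lists were fixed before the data were examined, 41 in all with 905 entries. Of these entries 894 matched the table by symbol, 4 through an older symbol and 7 not at all. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 41 lists. Beside it stand camera with an estimated correlation, which allows for genes that vary together between mice, and fry. The mean log2 CPM of each list per library was compared between diets with a two-sided exact permutation test. Counts of list members that rose or fell use the adjustment over all genes tested, and a second count is adjusted over the list alone.

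Genes named in the text follow a rule fixed before the data were examined. The rule takes up to 10 higher and 10 lower protein-coding genes with the largest fold changes among those called, with a mean of at least 5 CPM and with no overlap between the diets' libraries, leaving out symbols that are only numbered predictions. It takes up to 4 tested members of each list with the smallest p-values, those of at least 1 CPM first. It always takes Ern1, Xbp1, Ins1, Ins2, Gcg, Sst and Mki67. Genes outside the rule are marked where they appear. Some genes that the rule takes are not reported here, and they stayed in the list tests.

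The tests were checked on simulated counts made from the means, dispersions and library sizes of these 10 libraries over 15104 genes. The changed genes and the list members were drawn only from genes with a mean of at least 5 CPM. In that simulation of western diet against chow, edgeR recovered 26 of 50 genes changed 1.25-fold, 46 of 50 changed 1.5-fold, 49 of 50 changed 2-fold and 48 of 50 changed 4-fold, and called 6 of 14784 unchanged genes. Over 14921 simulated genes camera found all 3 lists of 40 genes raised 1.15-fold, with the preset and with the estimated correlation, and called 0 of 38 unchanged lists in both cases. Fry found the same 3 and called 1 of 38 unchanged lists. The simulated genes varied independently, so this says nothing about lists whose genes vary together.

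After these choices, the alternatives tried were RLE and upper quartile factors, no filter and a filter at 5 CPM, DESeq2 1.42.0, limma-voom, no robust moderation, protein-coding genes only, the mean of acinar markers as a covariate, mouse number as a block, and leaving out each mouse in turn. Chosen after seeing the data were the immediate early list mean as a covariate, exact permutation tests of the list means as an alternative to camera, and leaving out 2 libraries together. The table held counts, so alternatives for the pseudocount of normalized values did not apply. No library pair was identical, and counts of 2 libraries of the same diet differed beyond sampling noise in all 20 pairs (chi-square per degree of freedom 6.59 to 18.4), so each library was counted as 1 mouse.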

Results

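The islet transcriptome was measured by RNA sequencing in 5 male mice fed a western diet for 4 weeks and in 5 fed standard chow. Islets are the endocrine clusters of the pancreas and consist mostly of insulin-producing beta cells. Total counts per library ranged from 1.65e+07 to 2.39e+07 with no detectable difference between the diets (two-sided exact permutation p = 0.841, n = 5 per diet). The insulin gene Ins2 took between 16.02% and 18.6% of the counts of a library. Fewer genes had a read on western diet, 21720 ± 413 against 22436 ± 433 on chow (SD, n = 5 per diet, two-sided exact permutation p = 0.0317). The 10 most abundant genes took 30.3% ± 0.818 of the counts on western diet and 29.0% ± 0.689 on chow (SD, n = 5 per diet, two-sided exact permutation p = 0.0317). The first principal component held 24.2% of the variance and separated the diets. Chow cage 3 mouse 1 lay farthest out on it, and the western diet mouse of cage 2 lay nearest to chow.

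The series title names the stress sensor IRE1 alpha and expansion of the Golgi during early compensation by beta cells, and these samples allow the comparison of the diets. On western diet 796 genes rose and 831 fell among 15104 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small, with a median log2 fold change of 0.27 among genes that rose and -0.38 among genes that fell. Of 89 called genes beyond 1 on the log2 scale, 81 fell. The libraries of the diets did not overlap for 1037 of the called genes. Of all tested genes 8.85% separated in this way, against 0.794% by chance. The count of 1627 called genes was 938 without chow cage 3 mouse 1, 1050 without chow cage 3 mouse 3, 985 without western diet cage 4 mouse 4 and 1055 without western diet cage 4 mouse 5. The corresponding counts of genes that rose were 376, 431, 400 and 476. Since no cage held both diets, diet and cage cannot be told apart.

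Inducible heat shock genes fell most among called protein-coding genes of at least 5 CPM. Hspa1b and Hspa1a encode nearly identical HSP70 chaperones, so the split of reads between them is uncertain. Hspa1b (ENSMUSG00000090877, GRCm38 chromosome 17, 34956436 to 34959238) had 71.3 ± 17.9 CPM on western diet and 638 ± 147 on chow (SD, n = 5 per diet), a log2 fold change of -3.16 ± 0.24 (SE, edgeR adjusted p = 3.0e-04). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) fell by 3.05 ± 0.19 on the log2 scale. Dnajb1 (ENSMUSG00000005483, chromosome 8, 83608193 to 83612653), which encodes an HSP40 partner of HSP70, fell from 772 ± 93.1 to 227 ± 28.3 CPM. The other genes with the largest decreases, among called protein-coding genes of at least 5 CPM with no overlap between the diets, were Rbm15b (-1.63), which lies within the span of Manf so that its reads are uncertain, the collagen receptor gene Itga2 (-1.60), the activity-induced transcription factor gene Npas4 (-1.58), the NF-kB subunit gene Relb (-1.51), Rnd3 (-1.46), which encodes a small GTPase-like regulator of the cytoskeleton, the NF-kB inhibitor gene Tnfaip3 (-1.40) and Ddit3 (-1.36), which encodes CHOP. The Tnfaip3 call was lost without western diet cage 4 mouse 2 (edgeR adjusted p = 0.077), mouse 5 (0.0852) or mouse 4 (0.0768), and without chow cage 3 mouse 1 (0.0825), mouse 2 (0.059), mouse 3 (0.056) or mouse 4 (0.058).

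Increases were smaller among called protein-coding genes of at least 5 CPM with no overlap between the diets, while 8 called genes outside these limits rose by more than 1 on the log2 scale. Mdm1 (ENSMUSG00000020212, chromosome 10, 118141811 to 118168997) rose from 130 ± 10.3 to 255 ± 67.9 CPM (SD, n = 5 per diet, log2 fold change 0.98 ± 0.17 SE, edgeR adjusted p = 0.01). Next by log2 fold change within these limits came Aass (0.92), an enzyme of lysine breakdown, the small GTPase gene Rasd2 (0.91), Arhgap36 (0.87), the palmitoyltransferase family gene Zdhhc22 (0.85), the trafficking GTPase gene Rab31 (0.72), the glucocorticoid-induced Fkbp5 (0.72), Gramd2 (0.71), Rusc1 (0.67) and Ppp1r13l (0.66).

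**Figure D1:**
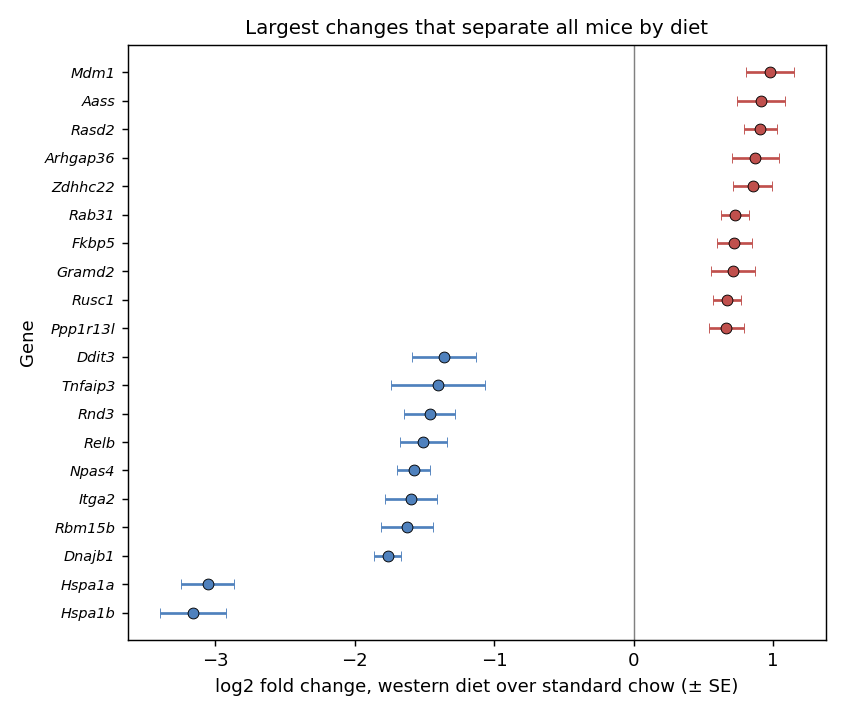
Log2 fold change (western diet over standard chow) of the 10 higher and 10 lower protein-coding genes with the largest changes among called genes of at least 5 CPM whose libraries did not overlap between diets; points are edgeR estimates and bars SE, n = 5 mice per diet. Decreases reach -3.16 for Hspa1b, while the largest increase shown is 0.98 for Mdm1.

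Some genes of the Golgi and of transport between the Golgi and the endoplasmic reticulum (ER) rose on western diet, 20 of 47 for Golgi structure, and most were not called. Among Golgi structure genes, the SNARE genes Stx5a (log2 fold change 0.40) and Gosr2 (0.28), the tether subunit gene Cog6 (0.34) and Tmf1 (0.24) rose. In the list of COPI coat and retrieval genes, the KDEL receptor genes Kdelr2 (0.33) and Kdelr1 (0.23) and the cargo lectin gene Lman2 (0.29) rose. These encode cargo receptors and not subunits of the coat, which returns proteins to the ER. Among genes of the COPII coat, which carries cargo out of the ER, Sec24d (0.49), Preb (0.40), Sec23ip (0.25) and Sar1a (0.22) rose. Among genes that build and trim N-glycans 13 of 34 rose, with Mogs (0.40), Alg2 (0.31), Ost4 (0.31) and Stt3b (0.30). Glycosylation enzymes of the Golgi went both ways: Mgat2 (0.59), B4galt6 (0.36) and Man1a (0.32) rose and the sialyltransferase gene St6gal1 (-0.29) fell.

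Of 47 Golgi structure genes 20 rose and 0 fell (30 and 0 adjusted over the list alone). The list mean was 6.85 ± 0.056 log2 CPM on western diet and 6.68 ± 0.064 on chow (SD, n = 5 per diet) with no overlap (two-sided exact permutation p = 0.00794, the smallest possible here, adjusted 0.0813). Of 17 COPI coat and retrieval genes 8 rose and 0 fell (15 and 1 adjusted over the list alone). The counts were 7 and 0 of 19 COPII genes (9 and 0), 13 and 0 of 34 N-glycan genes (18 and 0), and 6 and 2 of 40 Golgi glycosylation genes (6 and 2). Camera with its preset correlation placed all 5 lists higher, at adjusted p = 3.2e-10 for Golgi structure, 5.9e-06 for COPI, 2.3e-04 for COPII, 1.4e-06 for N-glycans and 0.039 for Golgi glycosylation. Each had adjusted p = 0.53 with an estimated correlation. The Golgi glycosylation call was lost without western diet cage 4 mouse 1 (0.054), mouse 2 (0.0839) or mouse 4 (0.0618), and without chow cage 3 mouse 1 (0.06) or mouse 3 (0.0601). Over all 41 lists camera called 16, 11 higher and 5 lower, and none was called with an estimated correlation, where 3 had an unadjusted p under 0.05 and fry called 11. Regrouping the libraries at random gave up to 19 lists by camera, so the number of lists alone does not set the real grouping apart.

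**Figure D2:**
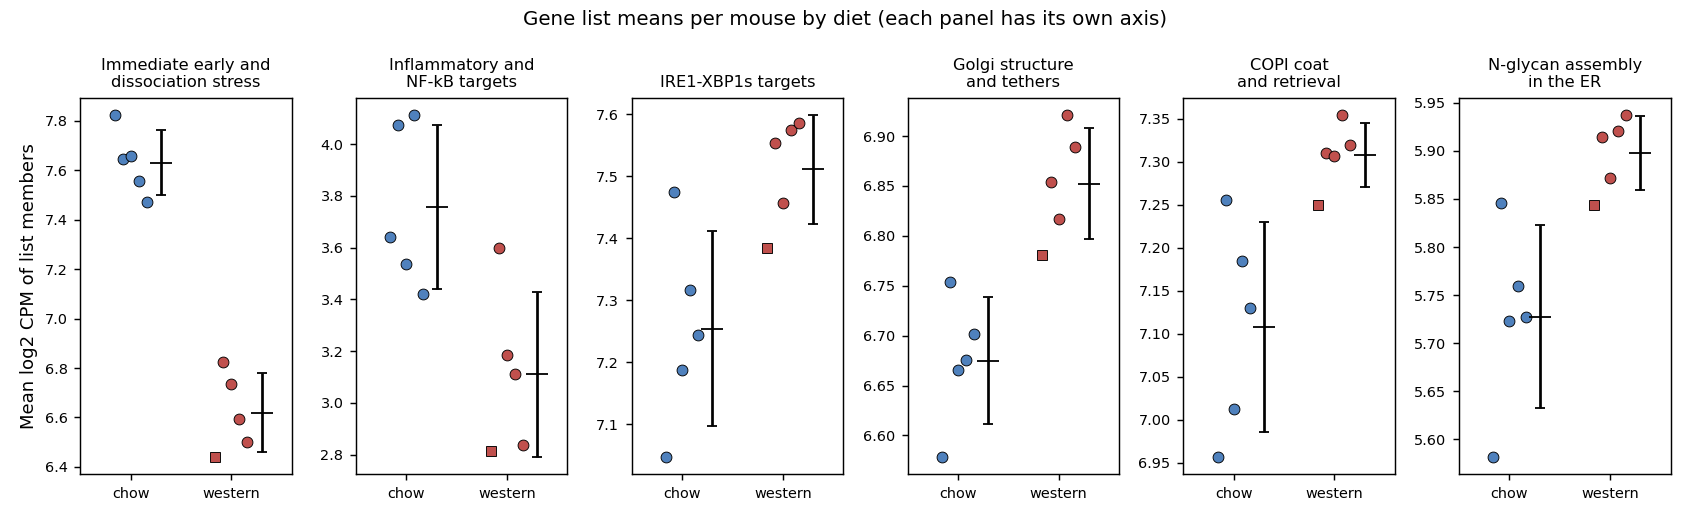
Mean log2 CPM of 6 gene lists (vertical axis, a separate scale per panel) in each mouse on standard chow and western diet; points are mice (n = 5 per diet), the square is the cage 2 mouse, and bars are mean ± SD. The immediate early list lay at 6.62 ± 0.159 on western diet and 7.63 ± 0.130 on chow, and the Golgi structure list at 6.85 ± 0.056 and 6.68 ± 0.064.

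The arms of the unfolded protein response were examined separately, and differences between them were not tested. The XBP1 target list shares members with other lists, such as Sec24d with COPII and Ost4 with N-glycans, so these lists are not independent. Splicing of Xbp1 was not measured here. Of 35 targets of spliced XBP1, the arm run by IRE1 alpha, 13 rose, among them Sec24d (log2 fold change 0.49), the ER sheet protein gene Ckap4 (0.43), Ost4 (0.31) and the translocon gene Sec62 (0.21). Hspa5, which encodes the ER chaperone BiP of the ATF6 arm, fell from 4312 ± 721 to 2505 ± 328 CPM (SD, n = 5 per diet, -0.78 ± 0.13 SE, edgeR adjusted p = 0.0073). In the PERK arm the amino acid transporter genes Slc7a1 (0.32) and Slc3a2 (0.30) rose, while Ddit3 (-1.36) and the phosphatase subunit gene Ppp1r15a (-0.46) fell. Eif2ak3, which encodes PERK itself, rose by 0.39, and Edem3 (0.31) and Ubxn4 (0.35) of ER associated degradation rose.

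Ern1 (ENSMUSG00000020715, chromosome 11, 106394650 to 106487852), which encodes IRE1 alpha, had 271 ± 28.2 CPM on western diet and 237 ± 15.8 on chow (SD, n = 5 per diet) and was not called (log2 fold change 0.19 ± 0.07 SE, edgeR adjusted p = 0.073). It was called with no filter on low counts (0.0445), and without western diet cage 4 mouse 1 (0.0118) or chow cage 3 mouse 2 (0.0469). Xbp1 (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893) was not called (0.15 ± 0.05 SE, edgeR adjusted p = 0.078). It was called without western diet cage 2 mouse 5, alone (0.0121) or with chow cage 3 mouse 1 (0.0331). Of 35 XBP1 targets 13 rose and 0 fell (26 and 0 adjusted over the list alone), of 18 ATF6 targets 1 and 1 (2 and 3), of 25 PERK targets 3 and 3 (3 and 3), of 22 degradation genes 5 and 0 (9 and 1) and of 8 sensor genes 3 and 0 (6 and 0). Camera placed the XBP1 (adjusted p = 1.5e-10), degradation (0.0044) and sensor (0.027) lists higher, each with adjusted p = 0.53 with an estimated correlation. The ATF6 list (0.961, and 0.987 with an estimated correlation) and the PERK list (0.241, and 0.839) were not called. The sensor call was lost without chow cage 3 mouse 1 (0.081) or mouse 4 (0.0594), and the PERK list was called higher under some alternatives, among them without western diet cage 2 mouse 5 (0.0436). With each mouse left out in turn, the edgeR call changed in 8 fits for the sensor gene Atf6b and in 7 for Creb3. For Sel1l of the degradation list the call changed in 5.

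Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, fell on western diet. Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), a subunit of the transcription factor AP-1, fell from 3355 ± 227 to 1656 ± 162 CPM (SD, n = 5 per diet, log2 fold change -1.02 ± 0.06 SE, edgeR adjusted p = 1.1e-07). The transcription factor gene Egr1 (-0.68) and the phosphatase gene Dusp1 (-0.67) fell as well. Among NF-kB targets Relb (-1.51) and the apoptosis inhibitor gene Birc3 (-0.69) fell. Of 24 genes in the immediate early list, which includes heat shock genes, 20 fell and 0 rose (23 and 0 adjusted over the list alone). Its mean was 6.62 ± 0.159 log2 CPM on western diet and 7.63 ± 0.130 on chow with no overlap (SD, n = 5 per diet, two-sided exact permutation p = 0.00794, adjusted 0.0813). Of 12 NF-kB targets 4 fell and 0 rose (7 and 0 adjusted over the list alone). Camera placed both lists lower (adjusted p = 1.7e-23 and 1.2e-04), with adjusted p = 0.198 with an estimated correlation for the immediate early list and 0.53 for the NF-kB list.

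Islet hormone genes showed no called change. Ins2 had 177427 ± 8751 CPM on western diet and 168735 ± 8701 on chow (SD, n = 5 per diet, edgeR adjusted p = 0.337), and Ins1, Gcg and Sst had log2 fold changes of 0.11 (adjusted p = 0.207), -0.02 (0.948) and -0.0042 (0.974). Genes of glucose sensing and beta cell identity moved both ways. G6pc2 (ENSMUSG00000005232, chromosome 2, 69211073 to 69227841), the islet glucose-6-phosphatase, rose from 2723 ± 207 to 3762 ± 109 CPM (SD, n = 5 per diet, edgeR adjusted p = 3.8e-05). The glucose transporter gene Slc2a2 (-0.54), the granule zinc transporter gene Slc30a8 (-0.27) and Foxo1 (-0.26) fell. Among secretory granule genes Scg2 (0.29), Rab3a (0.22) and Scg3 (0.19) rose and Rims2 (-0.23) fell. Of 25 beta cell genes 2 rose and 6 fell (2 and 9 adjusted over the list alone), and camera placed the list lower (adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). That call was lost without western diet cage 4 mouse 4 (0.0519) or chow cage 3 mouse 2 (0.0885). The granule list, with 3 of 22 higher and 1 lower (4 and 1 adjusted over the list alone), was not called (0.749).

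Several genes of cholesterol and fatty acid synthesis fell, and several of oxidative phosphorylation and ribosomes rose slightly. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), an early enzyme of cholesterol synthesis, fell from 69.9 ± 7.58 to 41.6 ± 3.47 CPM (SD, n = 5 per diet, edgeR adjusted p = 2.1e-05). The regulator gene Srebf2 (-0.26) fell with it, as did the desaturase genes Fads2 (-0.62) and Scd2 (-0.42) and the regulator gene Srebf1 (-0.31). The respiratory chain gene Ndufa4 (0.41), the ATP synthase gene Atp5g1 (0.31) and the lysosomal proton pump gene Atp6v0d1 (0.21) rose. Pklr (-0.38), a glycolytic enzyme, and the lysosomal regulator gene Tfe3 (-0.22) fell.

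Of 25 cholesterol genes 0 rose and 5 fell (0 and 9 adjusted over the list alone), of 47 oxidative phosphorylation genes 5 and 0 (5 and 0), of 46 ribosomal protein genes 7 and 0 (12 and 0) and of 30 lysosome genes 4 and 1 (8 and 2). Camera placed the cholesterol list lower (adjusted p = 0.0039) and the oxidative phosphorylation (7.5e-05), ribosomal (2.4e-07) and lysosome (0.0068) lists higher, each with adjusted p = 0.53 with an estimated correlation. Fatty acid synthesis (0 and 3 of 18, 1 and 4 adjusted over the list alone, camera adjusted p = 0.178) and glycolysis (3 and 2 of 18, 5 and 2, 0.358) were not called. With each mouse left out in turn, the edgeR call of Pgk1 (glycolysis) changed in 7 fits. Those of Aldoa (glycolysis), Atp5j (oxidative phosphorylation) and Neu1 (lysosome) changed in 6 each. None of 24 fatty acid oxidation genes (0.178) or 12 mitochondrially encoded transcripts (0.961) was called by edgeR, over all genes or adjusted over the list alone, with Acadvl at 0.19 (adjusted p = 0.1) and mt-Co1 at -0.07 (0.739).

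Some genes of DNA replication fell. The helicase genes Mcm5 (log2 fold change -0.86) and Mcm6 (-0.63) fell, while the cyclin gene Ccnd1 (0.24) rose. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of dividing cells, had 3.16 ± 1.22 CPM on western diet and 4.72 ± 0.612 on chow (SD, n = 5 per diet) and was not called (edgeR adjusted p = 0.097). Among the alternatives that called it were those without western diet cage 2 mouse 5, alone (0.0285) or with chow cage 3 mouse 1 (0.0371). In the list: cell cycle and proliferation, 1 of 38 genes rose and 4 fell (1 and 4 adjusted over the list alone), and it was not called (camera adjusted p = 0.15). It was called lower without western diet cage 2 mouse 5 (0.0192), without chow cage 3 mouse 3 (0.0493), and without western diet cage 2 mouse 5 and chow cage 3 mouse 1 together (0.0103), among other alternatives. Igfbp5 (-0.57), a binding protein of insulin-like growth factors, was among 2 genes of 8 in the serotonin and lactogen response list that fell, with 0 higher (0 and 2 adjusted over the list alone, camera adjusted p = 0.178). The list: serotonin and lactogen response was called lower without western diet cage 2 mouse 5 and chow cage 3 mouse 1 together (0.0267).

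Some duct markers fell. The keratin genes Krt8 (log2 fold change -0.85) and Krt19 (-2.64) fell, Krt8 from 333 ± 74.2 to 186 ± 22.1 CPM (SD, n = 5 per diet, edgeR adjusted p = 0.0094). Krt19 was low, at 0.24 to 1.07 CPM in western diet libraries and 1.95 to 6.69 in chow libraries. Krt8 was far more abundant, and which cells gave its reads was not determined. Of 13 duct markers 3 fell and 0 rose (3 and 0 adjusted over the list alone), and camera placed the list lower (adjusted p = 0.03, and adjusted p = 0.53 with an estimated correlation). That call was lost without western diet cage 2 mouse 5 (0.108) or chow cage 3 mouse 4 (0.0594), and with a minimum of 5 CPM (0.219). Acinar markers showed no detectable difference, at 5.43 ± 1.13 log2 CPM on western diet and 5.41 ± 0.774 on chow (SD, n = 5 per diet, two-sided exact permutation p = 0.976). Of other cells in the preparations, the endothelial receptor gene Kdr (-0.28), the collagen gene Col6a3 (-0.98), the pericyte receptor gene Pdgfrb (-0.44) and the macrophage complement gene C1qa (-0.51) fell. They were the only called members of their lists, 1 of 15 endothelial, 2 of 13 stellate and fibroblast and 1 of 19 macrophage markers. Of the macrophage markers 14 had a positive log2 fold change.

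The authors' deposited table called 1948 genes at the same threshold, 934 higher and 1014 lower on western diet. Of these, 1626 were also called with edgeR here, all with the same sign, and 1 gene was called only here. Across tested genes, which are not independent replicates, the log2 fold changes of both had a Pearson r of 0.9999.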

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

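The tests of handling between cages and of exonic reads of the neighbouring gene were chosen after the result was seen, as was the reading of the read-through test as undecided, and the immediate early covariate was added after seeing the data.

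Single mice stood apart from the other 4 of their diet in 24 of 450 groups of values, by a gap to the nearest mouse of over 0.71 of the whole range, and chance gives about 22.5. The highest number for a mouse was 5, for western diet cage 4 mouse 1. On chow, cage 3 mouse 3 had the lowest mean of the fatty acid synthesis list (4.97 log2 CPM) and of the Schwann cell list (1.88). Western diet cage 2 mouse 5 had the lowest mean of the adipocyte list (2.34) and the lowest Herpud1, an ER stress gene (383 CPM). In western diet cage 4 mouse 1 the exocytosis gene Rims2 was lowest (53.8 CPM), and Smad3 (7.05), Birc3 (11.2), the antibody gene Igkc (60.5) and the antigen presentation gene H2-Ab1 (61.4) were highest. In western diet cage 4 mouse 5 Nfib (5.27 CPM), Cox6b1 (61.7) and mt-Co3 (54.99) were highest, and in cage 4 mouse 2 Pmp22 (8.93) was.

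On chow, cage 3 mouse 1 had the lowest Rab3a (87.3 CPM) and the highest Igfbp5 (28.7), Ttr (1274) and Gcg (14250.1), the glucagon gene. Cage 3 mouse 2 had the highest Pgam1 (78.9 CPM), Srxn1 (57.1) and Pdyn (186), and cage 3 mouse 4 the highest Sertm1 (3.04). Cage 3 mouse 5 had the highest Muc1 (5.00 CPM) and the highest antibody genes Ighm (24.01) and Igkc (14.2).

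Immediate early and heat shock genes such as Jun and Hspa1b fell on western diet. Different amounts of acinar tissue are argued against, since the acinar marker mean was 5.43 ± 1.13 log2 CPM on western diet and 5.41 ± 0.774 on chow (SD, n = 5 per diet). With that mean as a covariate 20 of 24 members were still called lower (median log2 fold change -0.85). Means so alike left the covariate test little room to come out otherwise. Collection at another time of day stays open, as 4 clock genes of one phase (-0.34 to 0.50, none called) and 7 of the opposite phase (-1.18 to -0.01, none called, with Nr1d1 left out because its fall by 1.05 had been seen) differed by 0.46 ± 0.387 on the log2 scale on average (SE, n = 5 per diet, two-sided exact permutation p = 0.333). Handling that differed between cages cannot be told apart from diet: the cage 2 western diet mouse lay 0.22 log2 CPM from the cage 4 mean and 1.19 from chow, but there was only 1 chow cage. An effect of the diet itself stays open, as untested.

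Of 47 Golgi structure genes 20 rose on western diet, Stx5a and Cog6 among them, and 27 were not called. Gene length is argued against. The median log2 fold change of the Golgi structure list was 0.16 after the trend on length and expression was removed and 0.155 before. The bootstrap SE of 0.028 is over genes, not mice. Scaling or expression level is argued against as well, since 100% of 10000 random lists matched on expression had a lower median, with a highest of 0.105. Those lists drew genes independently, so they do not allow for genes that vary together between mice. A handling difference shared with the immediate early genes stays open, because with their mean as a covariate the diet effect on the Golgi list was 0.066 log2 CPM (95% interval -0.30 to 0.44) against 0.177 without it, and that mean follows diet too closely (r = -0.968) for a separation. Diet itself stays open, as untested.

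Transcripts inside or beside 4 genes of ER proteins, of which only Hspa5 was itself called lower and Atp2a2 encodes a calcium pump, had lower log2 fold changes than those genes: Rabepk (-1.33) beside Hspa5 (-0.78), Rbm15b (-1.63) beside Manf (-0.17), Gm15344 (-2.24) and 1810014B01Rik (-1.41) beside Hsp90b1 (-0.23), and Gm43360 (-1.21) beside Atp2a2 (0.08), all chosen after their values were seen. In 5 of 5 pairs the transcript fell by over 2 SE more than its neighbour. Because the pairs were chosen after these values were seen, that count cannot decide whether exonic reads of the neighbour are the cause. Reads from unspliced or read-through RNA stay open for these transcripts. Other features of stress genes differed from those of other genes by -0.054 on the log2 scale (bootstrap SE 0.034, permutation p = 0.0948). That difference met the bound set beforehand against this cause. The 47 stress genes with such a feature had a median of 0.051 themselves, which made a fall of their features less likely. A fall was still possible, as Rbm15b and Gm43360 fell beside genes that were not called. For 9 of the 47 stress genes, which were called lower themselves, 10 features had a median of -0.02 (-0.76 to 0.20). Of these features 0 were called lower by edgeR, too few and too spread to decide. No biological explanation was tested.

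The count of 1627 called genes exceeded that of other groupings of the 10 libraries, whose highest was 13. It was matched in 1 of 100 splits, the real one, which always matches itself. The other splits mixed the diets, which adds the difference between diets to the spread within their groups. The real grouping stood out, but this does not exclude chance and does not part diet from cage. The number of lists called by camera, 16, was matched or exceeded in 14 of 100 splits, with a highest of 19, so chance cannot be excluded for that number.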

How the results depend on the processing

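The immediate early covariate, the exact permutation of list means as an alternative and the removal of 2 libraries together were chosen after seeing the data.

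The count of genes changed, western diet against standard chow, was 1627 and became 1596 with RLE factors, 1597 with upper quartile factors, 1572 with no filter, 1633 at 5 CPM, 1552 without robust moderation, 1612 among protein-coding genes, 1831 with the acinar covariate, 1948 with DESeq2 and 1477 with limma-voom. Without chow cage 3 mouse 1 and western diet cage 2 mouse 5 together, 1303 were called, and 2 lists were called newly, cell cycle and proliferation (0.0103) and serotonin and lactogen response (0.0267). Leaving out 1 library gave 938 to 1813, with 376 to 921 higher and 562 to 892 lower. Low counts were 938 without chow cage 3 mouse 1, 1050 without chow cage 3 mouse 3, 985 without western diet cage 4 mouse 4 and 1055 without western diet cage 4 mouse 5. All fits without 1 library had fewer samples, also the one with 1813 (without western diet cage 2 mouse 5), so sample number alone does not account for the low counts.

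Mouse numbers recur in both diets but mark different animals. With the number as a block 841 genes were called, 342 higher and 499 lower, 775 of them shared with the fit without it, and 19 lists, newly PERK targets (0.017), Schwann cell markers (0.0429) and the list: cell cycle and proliferation (0.0195). Mki67 was called too (0.0484). The 5 same-number pairs had correlations of -0.129 to 0.0483, against -0.206 to 0.224 for other pairs, and 1 western diet library correlated best with its own number, so the pairing has no footing in these data.

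With the immediate early mean as a covariate edgeR called 0 genes, 0 higher and 0 lower, with 622 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 2. That mean follows diet (r = -0.968), which inflates the variance of the diet effect 16.1 times. The loss can come from this inflation or from a difference shared with the immediate early genes, and the fit cannot tell them apart. Of the 1627 called genes 402 took the other sign, and among named genes these were Gramd2 (-0.25), Tnfaip3 (1.36), Ddit3 (0.55), Foxo1 (0.085), Ost4 (-0.083), Hspa5 (0.49), Ppp1r15a (0.21), Edem3 (-0.062), Edem2 (-0.091), Sec23ip (-0.022), Fads2 (0.61), Ndufa4 (-0.24), Cox6b1 (-0.076), Neu1 (-0.053), Bst2 (-0.13), Birc3 (0.050), Nfkbiz (0.65), Ndrg1 (0.65) and Krt8 (0.66), none of them called. Camera called 7 lists. Its adjusted p was 0.73 for beta cell identity, 0.307 for XBP1 targets, 0.287 for ER associated degradation, 0.464 for sensors, Golgi structure and Golgi glycosylation, 0.785 for COPI and COPII, 0.916 for N-glycans, 0.0605 for cholesterol synthesis and 0.567 for duct markers. Newly called were ATF6 targets (0.00587), PERK targets (7.1e-12) and cell cycle (0.00335). Direction changed for oxidative phosphorylation (0.464), NF-kB targets (0.233), acinar (1.5e-10) and macrophage markers (0.0402).

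For the 16 lists called by camera, the estimated correlation called 0, with 3 of 41 at an unadjusted p under 0.05. The adjusted p was 0.198 for the immediate early list and 0.53 for the other 15: beta cell identity, XBP1 targets, ER associated degradation, sensors, Golgi structure, COPI, COPII, Golgi glycosylation, N-glycans, cholesterol, oxidative phosphorylation, ribosomal proteins, lysosome, NF-kB and duct. Fry called 11 and lost beta cell identity (0.115), ER associated degradation (0.0843), sensors (0.0582), cholesterol (0.0843) and oxidative phosphorylation (0.0948). Exact permutation of list means called 0 after adjustment, with 4 lists at its smallest p of 0.00794. With 5 mice per diet that p cannot go lower. A list that fully separated the diets could therefore not pass the adjustment over 41 lists on its own. Its adjusted p was 0.0813 for Golgi structure, COPI, COPII, N-glycans, ribosomal, immediate early and duct lists, 0.0887 for beta cell identity, XBP1 and NF-kB, 0.093 for cholesterol and lysosome, 0.108 for oxidative phosphorylation, 0.145 for Golgi glycosylation, 0.171 for ER associated degradation and 0.212 for sensors. A minimum of 5 CPM lost Golgi glycosylation (0.166) and duct markers (0.219), and the cause was not tested.

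Leaving out 1 library gave 14 to 17 lists. The adjusted p ranged from 0.00334 to 0.0885 for beta cell identity, 0.00631 to 0.081 for sensors, 0.0228 to 0.0839 for Golgi glycosylation and 0.00577 to 0.108 for duct markers, and the other 12 called lists stayed called. Of 3884 comparisons of named genes with an alternative, 3546 kept their side of the threshold with no change of sign in a called value, and 19 reversed, all 19 with the immediate early covariate. Genes and lists past the threshold in neither fit changed sign 97 times. The simulated data set the limit of depth and sample number for genes of at least 5 CPM: edgeR found 26 of 50 with the smallest simulated change. Recovery of changed genes below 5 CPM was not simulated.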

Other observations

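The remaining lists gave few calls by edgeR. The antioxidant gene Srxn1 (log2 fold change 0.29) rose among NRF2 targets, and the antiviral gene Bst2 (0.65) rose among interferon response genes. Of 18 NRF2 targets 2 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.369), of 25 interferon genes 1 and 0 (1 and 0, 0.322) and of 11 hypoxia genes 0 and 1 (0 and 1, 0.961). None of 12 progenitor genes (0.961) or 14 genes normally silenced in islets (0.168) was called, over all genes or adjusted over the list alone, but the silenced gene list was called lower without western diet cage 4 mouse 1 (0.00989).

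Of 15 alpha cell markers 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.488). Of 8 delta cell markers 0 rose and 1 fell (1 and 1, 0.534). It was Bche, at 0.40 ± 0.074 CPM on western diet and 1.02 ± 0.23 on chow (SD, n = 5 per diet, edgeR adjusted p = 0.0145), chosen after its values were seen. The delta median was 0.01 and became -0.0022 with upper quartile factors. Endothelial markers had 0 higher and 1 lower of 15 (0 and 3, 0.15), stellate and fibroblast markers 0 and 2 of 13 (0 and 2, 0.231) and macrophage markers 0 and 1 of 19 (0 and 1, 0.941). None of 7 PP cell (0.349), 26 acinar (0.941), 8 lymphocyte (0.168), 6 erythroid (0.961), 6 Schwann cell (0.369) or 3 adipocyte markers (0.358) was called over all genes, while adjusted over the list alone 1 Schwann cell marker fell and 1 adipocyte marker rose. The lymphocyte list was called without chow cage 3 mouse 5 (0.0483). Median, mean and test differed in sign in 6 lists, namely secretory granule, progenitor, ATF6, mitochondrially encoded, alpha and delta.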
